A study of Mus musculus with 9 samples.

How the data were processed

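Total RNA of 3T3-L1 cells was measured on 9 single-colour oligonucleotide arrays, 1 sample per array, in 3 groups of 3: preadipocytes, control siRNA adipocytes and PPAR gamma siRNA adipocytes. Groups were taken from the sample labels. The labels give the siRNA amount as 2 or 3 nmol for both adipocyte groups, without saying which arrays had which, and the time from transfection to harvest is not given in the sources used here. The deposited values were log2 probe set summaries that the authors had normalised between arrays. Their log2 scale was read from their range of 2.41 to 14.59, as no source used here states it. The authors' notes name MAS5, RMA and the affy package 1.16.0 without a role or an order, and the background correction is not given in the sources used here. Array medians lay between 4.82 and 4.89, and the median absolute difference between replicates of a group ranged from 0.101 to 0.151. Raw array files were not used here.

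The values were used without further scaling. The 64 spike-in and control probe sets were left out of the tests, and the other 45037 were tested. The platform annotation listed 35890 probe sets, of which 932 had several genes. A gene was represented by the probe set of highest mean over the 9 arrays among those with a single gene symbol, which gave 18193 genes from 34945 probe sets, 9010 of them with several probe sets. The 10092 tested probe sets without a single gene counted in the adjustment only. Of these, 1689 were higher and 1100 lower in differentiation, 623 higher and 569 lower with PPAR gamma siRNA than control siRNA, and 946 higher and 675 lower with PPAR gamma siRNA than in preadipocytes.

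The 3 comparisons were made with limma 3.58.1 in R 4.3.3, from 1 linear model of the 9 arrays with a mean per group and moderated variances: control siRNA adipocytes minus preadipocytes (differentiation), PPAR gamma siRNA minus control siRNA (knockdown), and PPAR gamma siRNA minus preadipocytes. All tests were two-sided, p was adjusted by Benjamini and Hochberg over the 45037 probe sets of a comparison, and a gene was called at an adjusted p under 0.05. In simulated data with 200 changed genes per comparison and the spread of these arrays, the same fit called 2.0% of 1.2-fold, 66.0% of 1.5-fold, 96.0% of 2-fold and 100.0% of 4-fold changes between the siRNAs, and no unchanged genes. For differentiation these shares were 2.0%, 54.0%, 92.0% and 100.0%, with 3 unchanged genes called, and for PPAR gamma siRNA against preadipocytes 2.0%, 44.0%, 88.0% and 100.0%, with 3. Far more than 200 genes were called in each comparison of the data, which makes the adjusted threshold less strict there. The shares therefore do not give the sensitivity of the counts below, where small changes are called more often.

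The comparisons, the tests, the 20 gene lists, the rule for named genes and the alternative settings were chosen before the data were examined, except where the text says otherwise. The lists covered PPARG targets, fatty acid and triglyceride synthesis, lipid droplets and lipolysis, adipokines, insulin signalling, adipogenic transcription factors, anti-adipogenic and preadipocyte factors, PPAR and RXR receptors and cofactors, extracellular matrix, contractile genes, cell cycle, mitochondrial oxidation, brown and beige adipocytes, inflammatory, interferon and stress responses, markers of macrophages, endothelium and of bone, cartilage and muscle, and reference genes. Of 412 list entries, 381 were measured, and some genes stand in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 20 lists of a comparison. The named genes were Pparg, Gata2 and Gata3, the 10 largest rises and 10 largest falls of each comparison among called genes whose replicates did not overlap, up to 2 rising and 2 falling members of each list, and, for the move back, 5 raised genes with the largest fall, 5 lowered genes with the largest rise and the 5 genes raised at least 8-fold with the smallest knockdown change. The fraction of a gene's differentiation change undone was the knockdown change with its sign reversed, divided by the differentiation change, in percent. Lists were compared in this fraction after the values were seen, by two-sided permutation tests of 100000 resamples in which genes in both lists were left out.

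Alternatives were renewed quantile normalisation, centring on array medians, omission of dim probe sets, a fit of only the 2 groups compared, an intensity trend with robust variances, the mean of all probe sets of a gene, omission of probe sets of types x and s, a block of replicate number, a test against 1.2-fold, a 2-fold minimum, a 4-fold minimum for differentiation genes, an estimated correlation for the lists and the omission of each array in turn. Added after the values were seen were the omission of the 2 arrays of highest Actb 3' minus 5' difference in their adipocyte groups and that difference as a covariate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.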

Results

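Gene expression was measured on 9 single-colour oligonucleotide arrays of 3T3-L1 cells, a mouse fibroblast line that turns into fat cells when given a hormone cocktail. The arrays fell into 3 groups of 3: undifferentiated preadipocytes, adipocytes electroporated with a non-targeting control siRNA, and adipocytes electroporated with siRNA against PPAR gamma, the nuclear receptor that drives adipocyte differentiation. Adipocytes had been made with 1 µM dexamethasone, 10 µg/ml insulin and 0.5 mM of the phosphodiesterase inhibitor IBMX, and the siRNA was given 14 days after induction. Each array reported 45037 probe sets besides 64 controls, with values between 2.41 and 14.59 on the log2 scale and array medians between 4.82 and 4.89. Correlations between arrays ranged from 0.994 to 0.998 within groups, from 0.928 to 0.930 between preadipocytes and control siRNA adipocytes, from 0.969 to 0.973 between the adipocyte groups, and from 0.965 to 0.971 between preadipocytes and PPAR gamma siRNA adipocytes. The series describes the replicates as technical, so the p-values measure only the spread between these samples, and 3 arrays a group limit the precision. The siRNA and electroporation were given to adipocytes alone, so their effect cannot be separated from that of differentiation when adipocytes are compared with preadipocytes. The difference between the 3' and 5' probe sets of Actb, a sign of RNA integrity, was 0.30 ± 0.06 in preadipocytes, 1.04 ± 0.22 in control siRNA adipocytes and 0.79 ± 0.40 in PPAR gamma siRNA adipocytes (SD, n = 3). The same difference for Gapdh lay between -0.19 and 0.11 in all 9 arrays. The spike-in control BioB-5 stood at 7.38 ± 0.27 in preadipocytes, 8.60 ± 0.15 in control siRNA adipocytes and 8.27 ± 0.29 in PPAR gamma siRNA adipocytes. Its highest preadipocyte value, 7.60, lay below the lowest adipocyte value, 7.945. Another spike-in, CreX-3, had group means of 13.52, 13.74 and 13.67 in the same order. The BioB-5 difference lies along every comparison with preadipocytes, and its effect was not tested. Group levels below are means ± SD (n = 3), and changes are log2 differences between groups ± SE from 1 fit over the 9 arrays.

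Pparg, the target of the siRNA, was represented by 1 probe set. It stood at 8.22 ± 0.12 in preadipocytes, 12.79 ± 0.12 in control siRNA adipocytes and 9.59 ± 0.05 in PPAR gamma siRNA adipocytes. Differentiation raised it 23.7-fold (log2 change 4.57 ± 0.09, adjusted p = 1.29e-11), and the siRNA lowered it (log2 change -3.20 ± 0.09, adjusted p = 1.27e-09). It remained above preadipocytes by 1.36 ± 0.09 (adjusted p = 6.98e-07). Gata2, a transcription factor that holds back adipocyte differentiation and whose re-expression the series title names, went from 9.75 ± 0.06 in preadipocytes to 6.45 ± 0.34 in control siRNA adipocytes (log2 change -3.30 ± 0.19, adjusted p = 3.41e-08). With PPAR gamma siRNA it stood at 6.51 ± 0.36, a difference from control siRNA of 0.06 ± 0.19 that did not pass the test (adjusted p = 0.871). A second Gata2 probe set gave -2.57 in differentiation and -0.15 ± 0.10 with the siRNA (adjusted p = 0.366 for the latter). Gata3, a related factor, was lower in control siRNA adipocytes (log2 change -0.42 ± 0.15, adjusted p = 0.0386) and differed by -0.12 ± 0.15 between the siRNAs (adjusted p = 0.648). The differentiation call on Gata3 ended under 8 of the other settings run, and over all of them its adjusted p ranged from 0.0077 to 0.155 and its change from -0.81 to -0.31. The 8 were the quantile-normalised values, the median-centred values, a replicate block, and the omission of preadipocytes 1 or 2, control siRNA 2 or 3, or PPAR gamma siRNA 2. Arrays of cells in which Gata2 was expressed again were not analysed here.

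**Figure D1:**
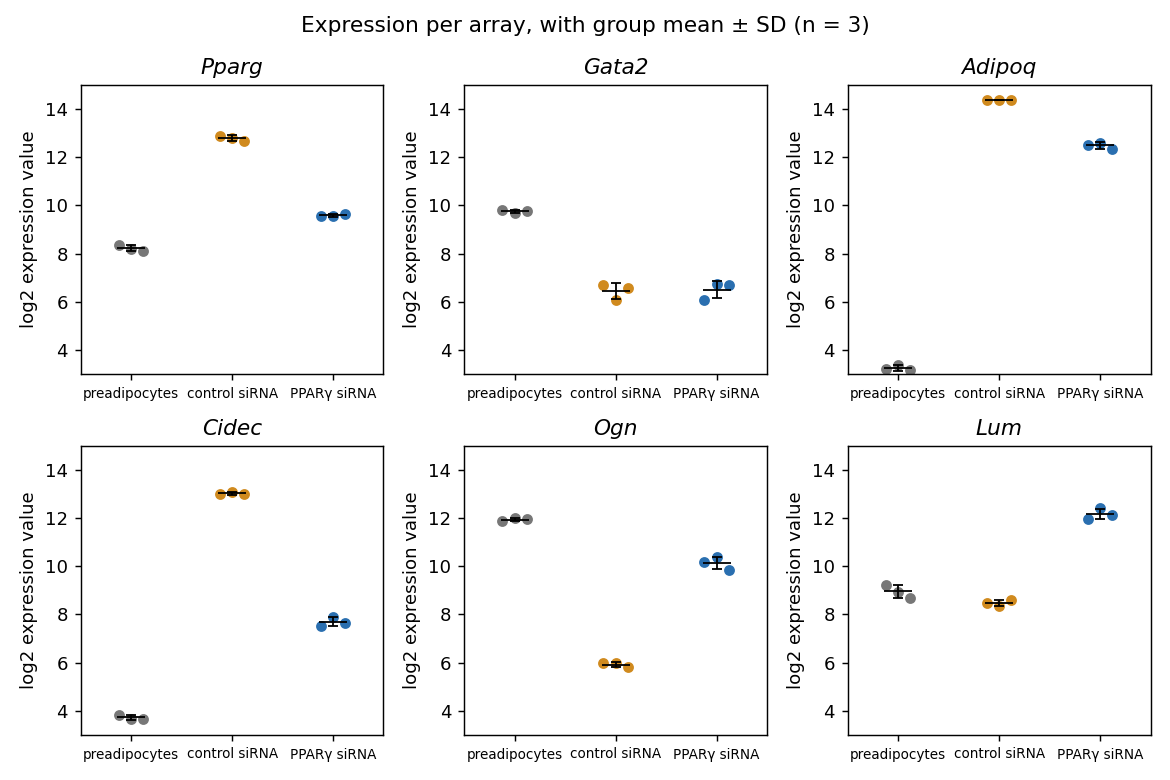
Level on the log2 scale of Pparg, Gata2, Adipoq, Cidec, Ogn and Lum in each of the 9 arrays, with the mean and SD of each group (n = 3). Pparg, Adipoq and Cidec were higher in control siRNA adipocytes than in preadipocytes and lower again with PPAR gamma siRNA, whereas Gata2 stood at 6.51 ± 0.36 with PPAR gamma siRNA beside 6.45 ± 0.34 with control siRNA.

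The comparison of control siRNA adipocytes with preadipocytes asked which genes mark the differentiated state. Among the 10 largest rises, Adipoq, which encodes the hormone adiponectin, went from 3.26 ± 0.12 to 14.37 ± 0.02, the fatty acid transporter Cd36 rose by 9.92 ± 0.10, the lipid droplet protein Cidec by 9.30 ± 0.10 and the fatty acid chaperone Fabp4 by 8.86 ± 0.09. Among the genes that fell were the plasminogen activator Plat at -6.02 ± 0.10, the matrix proteoglycan Ogn at -6.02 ± 0.12, the Wnt-binding protein Sfrp2 at -5.73 ± 0.25 and the metalloproteinase inhibitor Timp2 at -5.72 ± 0.10. In all, 4932 genes were higher and 4495 lower of 18193 tested, 1607 and 1937 of them by at least 2-fold. At least 8-fold changes were seen for 238 higher and 236 lower genes. The other genes of the 10 largest rises were the lipolysis inhibitor G0s2 (9.18 ± 0.12), the lipogenesis factor Thrsp (8.68 ± 0.09), the plasma proteins Orm1 (8.65 ± 0.10) and Hp (8.35 ± 0.14), the aldehyde dehydrogenase Aldh1a7 (8.58 ± 0.12) and Mrap (8.28 ± 0.11), which brings the corticotropin receptor to the cell surface. The remaining large falls were those of Cmtm3 (-5.94 ± 0.20), Sned1 (-5.67 ± 0.18), Psrc1 (-5.57 ± 0.16), the prokineticin receptor Prokr1 (-5.52 ± 0.21), the chemokine Cxcl5 (-5.42 ± 0.17) and follistatin, Fst (-5.34 ± 0.24). Among these 20 genes, picked from called genes whose arrays did not overlap between the groups, the adjusted p was at most 5.35e-09. Of all genes, 61.5% had arrays that did not overlap, where chance gives 10%. Genes close to the array floor or to its highest values in one group can have understated folds. Adipoq, at 14.37 in control siRNA adipocytes, stood near the highest value of any array, 14.59. Whether the signal was saturated there was not tested.

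The lists of lipid genes moved upwards in differentiation. Of 24 measured PPARG target genes, 22 rose and 2 did not pass the test (median log2 change 4.70, camera adjusted p = 1.29e-16). Fatty acid and triglyceride synthesis had 21 of 23 genes higher, among them Thrsp and Gpd1 (7.49 ± 0.13), with the elongase Elovl6 lower, at 6.54 ± 0.31 against 7.74 ± 0.33 in preadipocytes (median 2.58, adjusted p = 3.70e-12). Lipid droplet and lipolysis had 15 of 18 higher and the droplet coat gene Plin3 lower at -1.29 ± 0.10 (median 4.52, adjusted p = 2.45e-10). Adipokines and secreted proteins had 12 of 16 higher and none lower (median 2.53, adjusted p = 4.33e-09). Mitochondrial oxidation had 22 of 23 higher, led by the carnitine palmitoyltransferase Cpt2 (3.32 ± 0.10) and by Hadhb (3.10 ± 0.08) of fatty acid beta-oxidation, while Cpt1a fell by 0.74 (median 2.18, adjusted p = 8.08e-13). These 5 lists also passed with an estimated correlation, at adjusted p = 0.0027, 0.0428, 0.0027, 0.0033 and 0.0027 in the order given. Insulin signalling and glucose uptake had 14 of 19 higher and 4 lower (median 1.10, adjusted p = 0.0029, and adjusted p = 0.118 with an estimated correlation), including the insulin-responsive glucose transporter Slc2a4 at 4.92 ± 0.23 and the kinase Akt1 at -1.27 ± 0.14. Brown and beige adipocyte genes had 8 of 14 higher and 1 lower, with Cidea at 6.09 ± 0.14 and the cytochrome oxidase subunit Cox7a1 at 5.90 ± 0.11. Their median was 0.42 (adjusted p = 0.0050, and adjusted p = 0.0634 with an estimated correlation). PPAR and RXR receptors and cofactors had 9 of 14 higher and 2 lower, with Ppargc1b at 4.65 ± 0.08. Their median was 0.59 (adjusted p = 0.0164, and adjusted p = 0.0971 with an estimated correlation). The Actb 3' minus 5' difference was higher in control siRNA adipocytes than in preadipocytes in all arrays, alongside each of these lists.

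The lists of matrix, cytoskeleton and proliferation moved downwards, and each lost its call with an estimated correlation. Fibroblast and extracellular matrix genes had 19 of 24 lower, including the metalloproteinase Mmp3 (-4.88 ± 0.14) and the collagen cross-linking enzyme Lox (-4.49 ± 0.10), with Col15a1 higher at 1.17 ± 0.17. Their median was -1.51 (adjusted p = 1.18e-09, and adjusted p = 0.136 with an estimated correlation). Contractile and cytoskeletal genes had 17 of 20 lower and none higher, including Cnn2 (-4.39 ± 0.12) and filamin, Flna (-3.32 ± 0.15). Their median was -2.39 (adjusted p = 9.57e-10, and adjusted p = 0.118 with an estimated correlation). Cell cycle genes had 24 of 25 lower, with cyclin D1, Ccnd1, at -3.72 ± 0.15 and the spindle checkpoint kinase Bub1 at -3.70 ± 0.30. Their median was -2.26 (adjusted p = 2.48e-12, and adjusted p = 0.126 with an estimated correlation). Anti-adipogenic and preadipocyte factors had 16 of 24 lower and 2 higher, with Zfp521 at -4.55 ± 0.12 and Dlk1, a preadipocyte surface protein, at -3.37 ± 0.20. Their median was -0.96 (adjusted p = 9.80e-06, and adjusted p = 0.0763 with an estimated correlation). Inflammatory response genes had 10 of 23 lower and 4 higher, with the receptor Tlr2 at -3.07 ± 0.15 and the acute-phase gene Saa3 at 1.24 ± 0.12. Their median was -0.13 (adjusted p = 0.0093, and adjusted p = 0.0634 with an estimated correlation).

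The remaining lists did not pass camera in differentiation. Adipogenic transcription factors had 9 of 21 higher and 7 lower, with Klf15 at 7.35 ± 0.13 and Klf5 at -2.15 ± 0.19, a median of -0.24, a mean of 0.70 and a test direction upwards (adjusted p = 0.706). Interferon response genes had 5 of 20 higher and 8 lower (median -0.35, adjusted p = 0.208). Stress and unfolded protein response genes had 8 of 23 higher and 7 lower, with the chaperone Dnajb9 at 2.24 ± 0.09, a median of 0.0027, a mean of 0.14 and a test direction downwards (adjusted p = 0.925). Among markers of other cell types, macrophage genes had 4 of 14 higher and 1 lower (median 0.12, adjusted p = 0.423), with Cd68 at 1.35 ± 0.22. Endothelial genes had 1 of 12 higher and 3 lower, with a median of 0.12, a mean of -0.10 and a test direction downwards (adjusted p = 0.731). Bone, cartilage and muscle genes had 5 of 13 higher and 2 lower (median 0.16, adjusted p = 0.382), and reference genes had 3 of 11 higher and 6 lower (median -0.25, adjusted p = 0.382). Adjusted over the list alone, the counts of lower genes were 10 in adipogenic transcription factors, 17 in anti-adipogenic factors and 9 in interferon response, and all other counts of this comparison were equal to those over all genes tested. With dim probe sets left out, which drops genes from the lists, the median of the members left was 5.89 for brown and beige genes. It was -1.83 for inflammatory genes and 4.04 for adipokines. Such a shift can come from the loss of dim members alone. The inflammatory median was -0.66 with the mean of all probe sets and -0.24 without preadipocytes 2, and that of brown and beige genes was 0.68 with the Actb difference as a covariate. Chosen after the values were seen, a fit with the Actb difference as a covariate gave 3365 higher and 3877 lower genes, and a fit without control siRNA replicate 1 and PPAR gamma siRNA replicate 3, the arrays of highest Actb difference, gave 4629 and 4487.

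**Figure D2:**
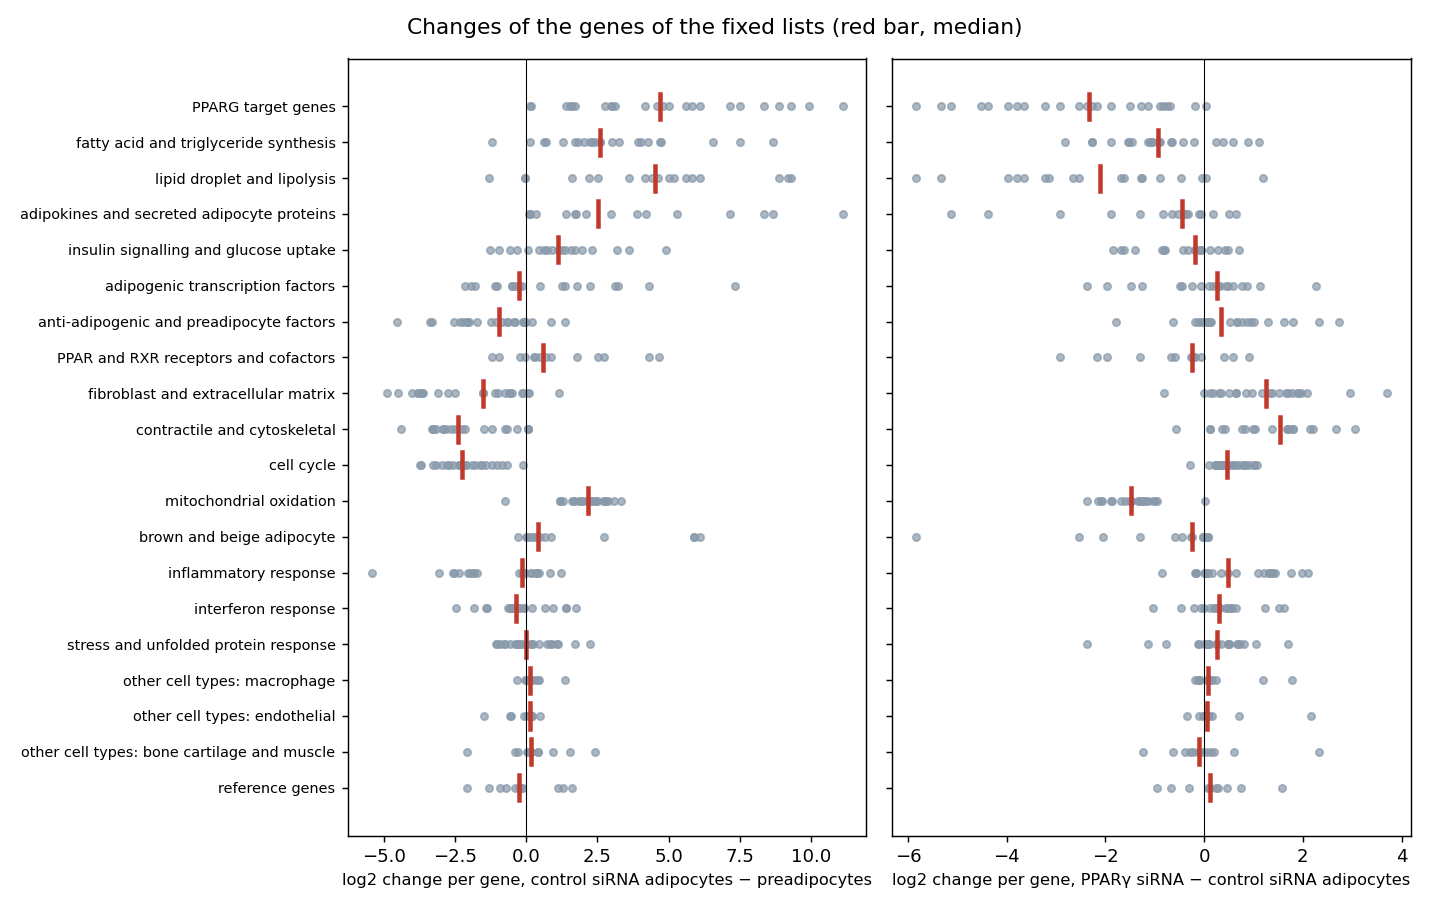
Log2 change of each measured gene of the 20 lists in differentiation (left) and with PPAR gamma siRNA (right), 1 point per gene, with the list's median as a red bar. The PPARG target genes had a median of 4.70 on the left and -2.32 on the right, and the fibroblast and extracellular matrix genes -1.51 and 1.25.

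The comparison of PPAR gamma siRNA with control siRNA asked what mature adipocytes lose and gain when the receptor is depleted. Fat-cell genes fell: the lipid droplet proteins Cidea, at 4.13 ± 0.25 with PPAR gamma siRNA against 9.97 ± 0.23 with control siRNA, and Cidec (-5.32 ± 0.10), the hormone resistin, Retn (-5.14 ± 0.11), and Pck1 (-4.53 ± 0.18), the key enzyme of glyceroneogenesis. Genes that rose included Timp2 at 4.50 ± 0.10, Ogn at 4.21 ± 0.12, the intermediate filament gene Synm at 4.18 ± 0.18, and the collagen-binding proteoglycan Lum at 12.16 ± 0.22 with PPAR gamma siRNA, above both control siRNA (8.46 ± 0.12) and preadipocytes (8.95 ± 0.26). In all, 3612 genes were higher and 2922 lower of 18193 tested, 1033 and 838 of them by at least 2-fold, and 28 and 56 by at least 8-fold. Other large falls were those of Rassf6 (-4.84 ± 0.10), the short-chain fatty acid receptor Ffar2 (-4.73 ± 0.13), B3galt2 (-4.41 ± 0.14), Hp (-4.37 ± 0.14), Aldh3b2 (-4.33 ± 0.08) and Lrrc39 (-4.27 ± 0.10). Other large rises were those of Lrrc75b (5.02 ± 0.20), Lhfp (4.69 ± 0.10), Olfml3 (4.03 ± 0.10), Mrgprf (3.91 ± 0.14), Cmtm3 (3.84 ± 0.20) and the aldehyde dehydrogenase Aldh3a1 (3.62 ± 0.11). The adjusted p of these 20 genes was at most 7.78e-08. Of all genes, 44.4% had arrays that did not overlap between the groups, with 10% given by chance. The probe set of Pck1 is of a type that may match transcripts of more than 1 gene.

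Lipid and mitochondrial lists moved downwards with PPAR gamma siRNA. Of the 24 PPARG target genes, 22 fell and 2 did not pass the test (median -2.32, adjusted p = 2.93e-20). Lipid droplet and lipolysis had 15 of 18 lower and Plin3 higher at 1.19 ± 0.10 (median -2.11, adjusted p = 2.44e-12). Mitochondrial oxidation had 22 of 23 lower and none higher, with Idh3a of the citric acid cycle at -2.38 ± 0.09 and the thiolase Acaa2 at -2.15 ± 0.08 (median -1.47, adjusted p = 8.84e-19). Adipokines and secreted proteins had 11 of 16 lower and 2 higher, with Sncg at 0.49 ± 0.10 and Lcn2 at 0.65 ± 0.17 (median -0.46, adjusted p = 9.64e-05). The call on Lcn2 ended without control siRNA 2, control siRNA 3 or PPAR gamma siRNA 1 (adjusted p from 0.0010 to 0.0561 over the settings run). These 4 lists passed with an estimated correlation too, at adjusted p = 0.0015, 0.0015, 0.0011 and 0.0217 in the order given. Fatty acid and triglyceride synthesis had 16 of 23 lower, with Dgat1, which makes triglyceride, at -2.82 ± 0.10 and Gpd1 at -2.27 ± 0.13. Their median was -0.93 (adjusted p = 9.43e-07, and adjusted p = 0.0999 with an estimated correlation). The 4 genes of this list that rose included the elongase Elovl6 (1.11 ± 0.20) and the desaturase Fads1 (0.89 ± 0.15). The Actb 3' minus 5' difference was 0.54, 0.56 and 1.25 in the PPAR gamma siRNA arrays and 0.91, 0.92 and 1.30 in the control siRNA arrays, beside these falls.

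Brown and beige adipocyte genes had 6 of 14 lower, led by Cidea and Cox7a1 (-2.53 ± 0.11). Their median was -0.25 (adjusted p = 0.0049, and adjusted p = 0.0663 with an estimated correlation), and -0.15 without PPAR gamma siRNA 3. PPAR and RXR receptors and cofactors had 6 of 14 lower and 3 higher, with Ppargc1b at -2.93 ± 0.08 and Rxrg at -2.16 ± 0.11. Their median was -0.25 (adjusted p = 0.0090, and adjusted p = 0.0921 with an estimated correlation). Insulin signalling and glucose uptake had 9 of 19 lower and 2 higher, with Irs2, a substrate of the insulin receptor, at -1.85 ± 0.17 and Pde3b at -1.68 ± 0.08. Their median was -0.19 (adjusted p = 0.0194, and adjusted p = 0.212 with an estimated correlation). It moved to -0.31 without control siRNA 2 or without PPAR gamma siRNA 3, -0.29 with the mean of all probe sets, -0.37 without x and s probe sets, -0.39 without the 2 arrays of highest Actb difference and -0.12 with that difference as a covariate. Adipogenic transcription factors had 6 of 21 higher and 6 lower, with a median of 0.25, a mean of -0.02 and a test direction upwards (adjusted p = 0.687). Members of this list moved apart, with Cebpa, a late factor, at -2.37 ± 0.17 and Cebpd, an early one, at 2.27 ± 0.14. Anti-adipogenic and preadipocyte factors had 12 of 24 higher and 2 lower, with Zfp521 at 2.74 ± 0.12, Sox9 at 2.33 ± 0.16 and Wnt5a at -1.78 ± 0.11. Their median was 0.34 (adjusted p = 0.0049, and adjusted p = 0.209 with an estimated correlation).

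Matrix, contractile and inflammatory lists moved upwards with PPAR gamma siRNA. Fibroblast and extracellular matrix genes had 19 of 24 higher, led by Lum (3.70 ± 0.14) and Lox (2.95 ± 0.10), with Col15a1 lower at -0.82 ± 0.17. Their median was 1.25 (adjusted p = 2.56e-10, and adjusted p = 0.153 with an estimated correlation). Contractile and cytoskeletal genes had 17 of 20 higher and 1 lower, with Cnn2 at 3.05 ± 0.12 and Flna at 2.68 ± 0.15. Their median was 1.53 (adjusted p = 8.90e-10, and adjusted p = 0.129 with an estimated correlation), and 0.97 with the mean of all probe sets. Cell cycle genes had 12 of 25 higher and none lower, with the replication helicase subunit Mcm6 at 1.08 ± 0.15 and Ccnd1 at 1.02 ± 0.15. Their median was 0.47 (adjusted p = 3.87e-04, and adjusted p = 0.473 with an estimated correlation). Inflammatory response genes had 13 of 23 higher and 1 lower, with the adhesion molecule Vcam1 at 2.10 ± 0.12 and Cxcl5 at 1.98 ± 0.17. Their median was 0.49 (adjusted p = 4.63e-04, and adjusted p = 0.0255 with an estimated correlation). Interferon response genes had 8 of 20 higher and 1 lower, with Ifit2 at 1.63 ± 0.21 and Oasl2 at 1.51 ± 0.23. Their median was 0.31 (adjusted p = 0.0325, and adjusted p = 0.627 with an estimated correlation). Among markers of other cell types, macrophage genes had 2 of 14 higher, Cd14 at 1.78 ± 0.10 and Cd68 at 6.56 ± 0.59 against 5.36 ± 0.06 with control siRNA, beside the matrix and inflammatory lists (median 0.08, adjusted p = 0.416). Endothelial genes had 2 of 12 higher, Ramp2 (2.16 ± 0.19) and Eng (0.70 ± 0.09) (median 0.05, adjusted p = 0.420). Bone, cartilage and muscle genes had 2 of 13 higher and 3 lower, with a median of -0.10, a mean of 0.02 and a test direction downwards (adjusted p = 0.519).

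Stress and unfolded protein response genes had 10 of 23 higher and 3 lower with PPAR gamma siRNA, with Gadd45b at 1.69 ± 0.15 and the chaperone Dnajb9 at -2.38 ± 0.09 (median 0.27, adjusted p = 0.0898). Reference genes had 3 of 11 higher and 3 lower (median 0.12, adjusted p = 0.638). Adjusted over the list alone, 23 PPARG target genes, 17 fatty acid synthesis genes and 7 receptors and cofactors were lower, 8 adipogenic factors and 11 stress genes were higher, and the cell cycle list had 16 higher and 1 lower. All other counts were equal to those over all genes tested. The interferon call ended without control siRNA replicate 2 (median 0.25, adjusted p = 0.0882), PPAR gamma siRNA replicate 1 (0.17, adjusted p = 0.225) or PPAR gamma siRNA replicate 3 (0.27, adjusted p = 0.0518), and with dim probe sets left out (0.33, adjusted p = 0.169), and the median was 0.48 without PPAR gamma siRNA replicate 2. Its adjusted p ranged from 9.28e-04 to 0.627 over the settings run. The insulin signalling call also ended with dim probe sets left out (median -0.19, adjusted p = 0.0609, in a range from 0.0043 to 0.212 over the settings run), a setting that moved the medians of brown and beige genes to -2.06, of inflammatory genes to 1.09, of adipokines to -0.73 and of anti-adipogenic factors to 0.60. Chosen after the values were seen, the fit with the Actb difference as a covariate gave 3671 higher and 2798 lower genes, and the fit without the 2 arrays of highest Actb difference gave 3153 and 2602.

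The comparison of PPAR gamma siRNA adipocytes with preadipocytes asked how far the depleted cells stood from the undifferentiated state. The largest rises over preadipocytes were those of Adipoq by 9.23 ± 0.10, Cd36 by 8.41 ± 0.10, G0s2 by 7.93 ± 0.12, Thrsp by 7.62 ± 0.09 and Fabp4 by 7.58 ± 0.09. Other fat-cell genes did not pass the test against preadipocytes, among them Cidea (0.25 ± 0.14, adjusted p = 0.231) and Pck1 (0.07 ± 0.18, adjusted p = 0.822). Genes still below preadipocytes included Mmp3 at -4.57 ± 0.14, Plat at -4.23 ± 0.10, the surface glycoprotein Pdpn at -3.82 ± 0.12, the matrix protein Fbln1 at -3.71 ± 0.16 and Prokr1 at -3.65 ± 0.21. In all, 3558 genes were higher and 3074 lower, 781 and 912 of them by at least 2-fold, and 96 and 36 by at least 8-fold. The other largest rises were those of Orm1 (7.36 ± 0.10), Apoc1 (7.03 ± 0.10), Itih4 (6.35 ± 0.09), Ces1f (6.35 ± 0.10) and Aldh1a7 (6.35 ± 0.12), and the other largest falls those of Gm2115 (-3.64 ± 0.22), Pla2g7 (-3.55 ± 0.13), the metalloproteinase inhibitor Timp3 (-3.46 ± 0.14), Cxcl5 (-3.44 ± 0.17) and Adgrg6 (-3.42 ± 0.13). The adjusted p of these 20 genes was at most 2.65e-07, and the probe set of Ces1f, like that of Pck1, may match more than 1 gene. Arrays did not overlap between the groups for 49.8% of all genes, against 10% by chance.

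Lists of fat metabolism stayed above preadipocytes and passed with an estimated correlation. Fatty acid and triglyceride synthesis had 21 of 23 genes higher and none lower. Their median was 1.66 (adjusted p = 2.98e-16, and adjusted p = 0.0203 with an estimated correlation). PPARG target genes had 18 of 24 higher and Pdk4 lower at -0.98 ± 0.14 (median 1.61, adjusted p = 1.32e-11). Lipid droplet and lipolysis had 13 of 18 higher (median 1.53, adjusted p = 7.02e-09), adipokines 13 of 16 (median 1.43, adjusted p = 3.35e-10) and mitochondrial oxidation 18 of 23 with 1 lower (median 0.67, adjusted p = 6.52e-07). With an estimated correlation these 4 lists each had adjusted p = 0.0060. Cell cycle genes had 24 of 25 lower, with Bub1 at -2.79 ± 0.30 and Ccnd1 at -2.70 ± 0.15. Their median was -1.56 (adjusted p = 2.98e-16, and adjusted p = 0.141 with an estimated correlation). Contractile and cytoskeletal genes had 15 of 20 lower and 2 higher, with Tpm1 at -2.52 ± 0.12 and Csrp1 at 1.04 ± 0.08. Their median was -0.74 (adjusted p = 9.38e-06, and adjusted p = 0.229 with an estimated correlation). Fibroblast and extracellular matrix genes had 14 of 24 lower, including Col1a1 at -2.37 ± 0.28, and 2 higher, Lum at 3.21 ± 0.14 and Fn1 at 1.27 ± 0.08. Their median was -0.54 (adjusted p = 3.77e-05, and adjusted p = 0.278 with an estimated correlation), and -0.90 with the mean of all probe sets. Another probe set of Fn1 was called in the opposite direction, and the mean over its probe sets was -0.05 (adjusted p = 0.821, in a range from 2.16e-09 to 0.821 over the settings run). The Actb 3' minus 5' difference was higher than in preadipocytes in each PPAR gamma siRNA array, beside these changes.

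Among regulators in the same comparison, insulin signalling had 12 of 19 higher and 3 lower, with Slc2a4 at 3.30 ± 0.23. Their median was 0.45 (adjusted p = 0.0044, and adjusted p = 0.144 with an estimated correlation). Anti-adipogenic factors had 11 of 24 lower and 3 higher, with Wnt5a at -3.02 ± 0.11. Their median was -0.16 (adjusted p = 0.0013, and adjusted p = 0.144 with an estimated correlation), and -0.24 without PPAR gamma siRNA 1. Adipogenic transcription factors had 13 of 21 higher and 5 lower, with Klf15 at 5.87 ± 0.13 and Srebf1, which switches on lipid synthesis, at 2.84 ± 0.09. Their median was 0.50 (adjusted p = 0.0222, and adjusted p = 0.278 with an estimated correlation). Brown and beige adipocyte genes had 4 of 14 higher, with Cox8b at 3.83 ± 0.11. Their median was 0.23 (adjusted p = 0.0305, and adjusted p = 0.141 with an estimated correlation). The lists that did not pass were PPAR and RXR receptors and cofactors with 6 of 14 higher and 1 lower (median 0.27, adjusted p = 0.0519), inflammatory response with 5 of 23 higher and 9 lower (median -0.27, adjusted p = 0.0723), and interferon response with 4 of 20 higher and 2 lower (median 0.07, adjusted p = 0.974). Stress genes had 8 of 23 higher and 2 lower (median 0.10, adjusted p = 0.195), and reference genes had 3 of 11 higher and 2 lower (median -0.13, adjusted p = 0.621). Macrophage genes had 2 of 14 higher, Cd68 at 2.55 ± 0.22 and Cd14 at 1.89 ± 0.10 (median 0.20, adjusted p = 0.0819). Endothelial genes had 2 of 12 higher and 1 lower (median 0.14, adjusted p = 0.557), and bone, cartilage and muscle genes had 4 of 13 higher (median 0.21, adjusted p = 0.200). Adjusted over the list alone, 22 fatty acid synthesis, 13 insulin signalling, 7 receptor and cofactor, 3 matrix, 20 mitochondrial and 7 inflammatory genes were higher, and 6 adipogenic factors and 10 inflammatory genes were lower. The remaining counts were equal.

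The call on adipogenic transcription factors against preadipocytes ended with the mean of all probe sets of a gene (median 0.14, adjusted p = 0.145), without the 2 arrays of highest Actb difference (0.44, adjusted p = 0.0525) and with that difference as a covariate (0.43, adjusted p = 0.0534), in a range from 0.0062 to 0.278 over the settings run. The call on brown and beige adipocyte genes ended with quantile-normalised values (median 0.19, adjusted p = 0.0816, in a range from 0.0078 to 0.141 over the settings run), and their median was 1.42 with dim probe sets left out. That setting also moved the medians of adipokines to 2.69 and of anti-adipogenic factors to -0.33. Chosen after the values were seen, the covariate gave 2677 higher and 2759 lower genes in PPAR gamma siRNA adipocytes than in preadipocytes, and the fit without the 2 arrays gave 3450 and 3092.

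Setting the knockdown beside differentiation asked how much of the adipocyte programme was undone. Of 1607 genes raised at least 2-fold in differentiation, 1356 (84.4%) fell with PPAR gamma siRNA, 45 (2.8%) rose further and 206 (12.8%) did not pass the test. Of 1937 genes lowered at least 2-fold, 1541 (79.6%) rose, 11 (0.6%) fell further and 385 (19.9%) did not pass. In 100 simulations with unchanged PPAR gamma siRNA arrays, 0 raised genes fell and at most 1 lowered gene rose, called with limma as in the data. The siRNA changed no gene in these simulations, so a count near 0 was fixed in advance. The simulations show only that noise of the shared arrays gives few such calls, and not that knockdown opposes differentiation. Independent lists of the observed sizes would share 258.1 and 384.6 genes, a number that leaves out the shared control arrays, from which part of the excess in these counts may come. The move back was partial: the median gene of the raised set lost 54.9% of its log2 rise (interquartile range 30.7% to 73.8%), and the median gene of the lowered set regained 50.2% of its fall (28.2% to 72.7%). Against preadipocytes, 1310 (81.5%) of the raised genes were still called higher and 1553 (80.2%) of the lowered genes still lower. Of the 238 genes raised at least 8-fold, 214 (89.9%) fell, and of the 236 lowered at least 8-fold, 216 (91.5%) rose. Raised genes with the largest falls were Cidea (-5.84 ± 0.14), Cidec, Retn, Rassf6 and Ffar2, and lowered genes with the largest rises were Lrrc75b, Lhfp, Timp2, Ogn and Synm. The genes raised at least 8-fold with the smallest change on knockdown were the sulfotransferase Sult1a1 (4.74 ± 0.12 in differentiation, -0.0017 ± 0.12 on knockdown), Parm1 (-0.0050 ± 0.10 on knockdown), the kinase Dapk1 (0.01 ± 0.12), the protease Prtn3 (0.02 ± 0.10) and the iron-regulating gene Hfe (0.05 ± 0.11), none of which passed the test.

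**Figure D3:**
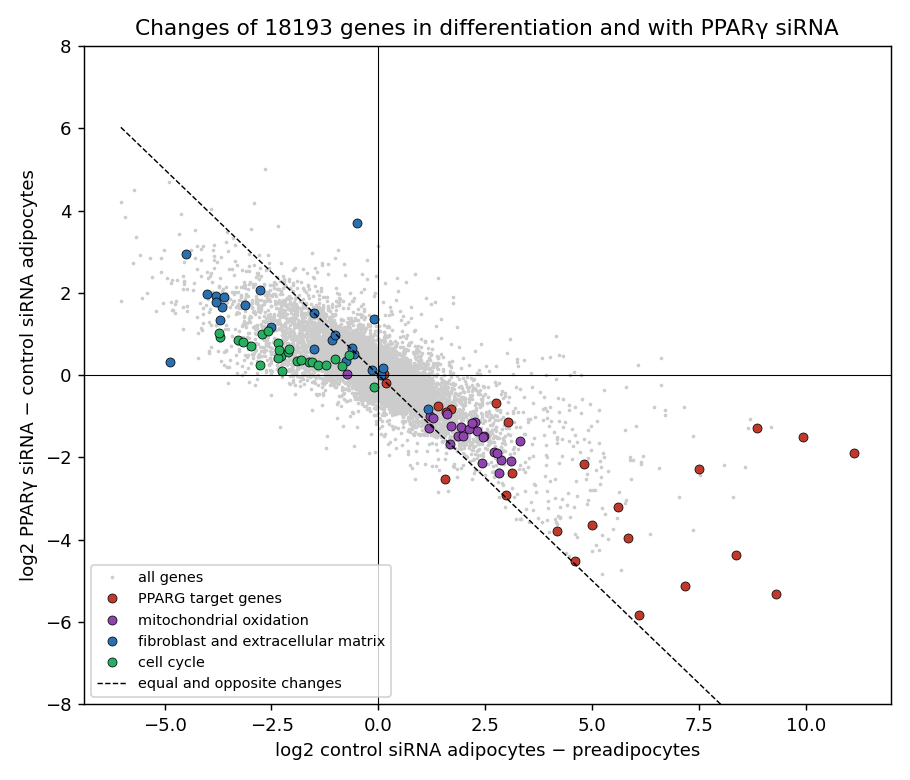
Log2 change with PPAR gamma siRNA (vertical) against log2 change in differentiation (horizontal) for 18193 genes, 1 point per gene, with 4 lists coloured and a dashed line where the changes are equal and opposite. The slope over all points was -0.482, between the dashed line and 0. Single genes lay outside that band, such as Pdk4, with 163.7% of its rise undone, and Wnt5a, which fell in both comparisons.

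Across the 18193 genes, the covariance of the knockdown and differentiation changes was -0.547, with Pearson's r = -0.792 and a slope of -0.482; genes are not independent replicates. Both changes use the control siRNA arrays, which gives a negative covariance without any effect. In 100 simulations with unchanged PPAR gamma siRNA arrays it lay between -0.0093 and -0.0037, and r between -0.0697 and -0.0284. The observed covariance minus the simulated median was -0.539. Chosen after the values were seen, the 6 ways of giving 1 control array to one change and the other 2 to the other, so that none was shared, gave covariances from -0.544 to -0.531. If the replicates are technical, as the series describes them, the simulations and this division cover array noise only. A deviation of a control sample common to the arrays would stay in both changes.

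Some lists differed in how far they moved back, a comparison chosen after the values were seen. Among members raised at least 2-fold, the median fraction of the differentiation change undone was 68.7% for mitochondrial oxidation (22 genes), 57.2% for lipid droplet and lipolysis (15), 56.9% for PPARG targets (22) and 32.0% for fatty acid and triglyceride synthesis (19). Among lowered members it was 66.5% for contractile genes (14), 50.7% for matrix genes (15) and 24.2% for cell cycle genes (22). In 9 two-sided permutation tests with 100000 resamples, fatty acid synthesis differed from mitochondrial oxidation (p = 1e-05, the smallest such resampling can give, adjusted p = 9e-05). In the same permutation tests, cell cycle genes differed from matrix genes (p = 2e-05, adjusted p = 9e-05) and from contractile genes (p = 7e-05, adjusted p = 2e-04). The permutation tests of fatty acid synthesis against PPARG targets (p = 0.0364) and against lipid droplet genes (p = 0.0353) each had an adjusted p of 0.0655. The other 4 tests did not pass, with adjusted p of 0.0937 for matrix against contractile, 0.140 for lipid droplet against mitochondrial, 0.144 for PPARG targets against mitochondrial and 0.819 for PPARG targets against lipid droplet genes. Genes of a list are not independent, so these p-values describe the lists and not repeats of the experiment.

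**Figure D4:**
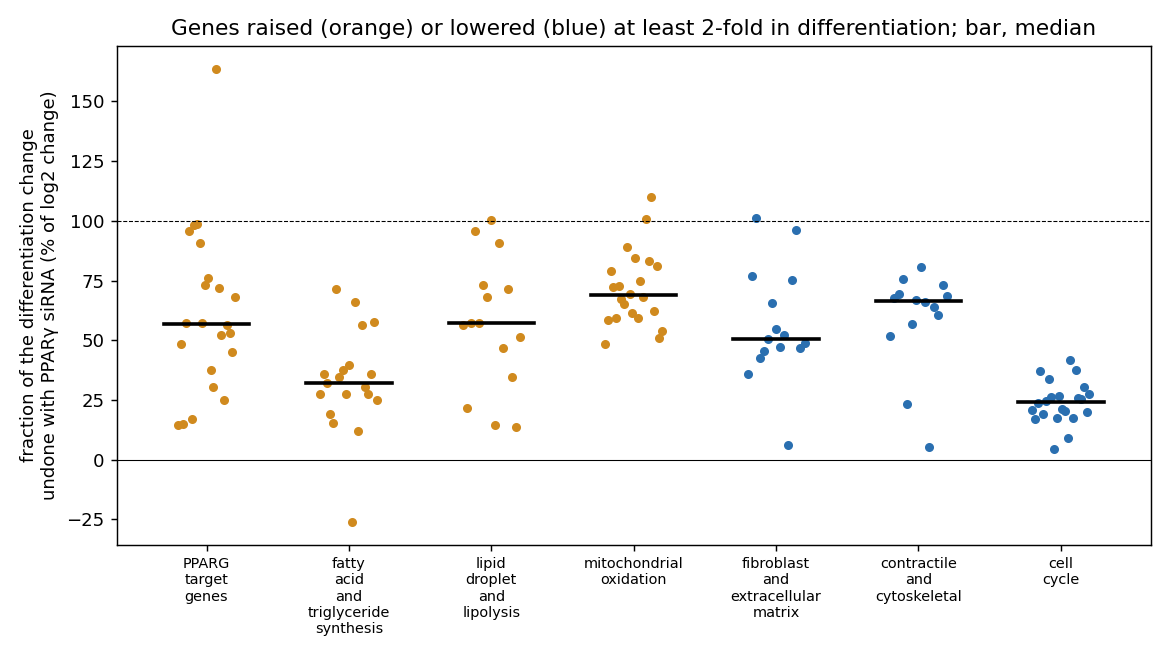
Fraction of the log2 differentiation change undone with PPAR gamma siRNA, in percent, for each gene of 7 lists raised (orange) or lowered (blue) at least 2-fold in differentiation, with the median as a bar. Mitochondrial oxidation genes had a median of 68.7% and cell cycle genes 24.2%.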

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

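The 6 counts of genes, 2 counts of genes moved back and the covariance took 185 values under other settings, and 169 of them stayed within 1.5 times the count, or within the spread of the covariance, with no change of direction. The settings without the 2 arrays of highest Actb 3' minus 5' difference and with that difference as a covariate were chosen after the data were seen. Genes of at least 2-fold numbered 1607 higher and 1937 lower in differentiation, 1033 and 838 with PPAR gamma siRNA against control siRNA, and 781 and 912 against preadipocytes, fewer by construction. A test against 1.2-fold left 2844 higher and 3293 lower in differentiation, 2131 and 1726 between the siRNAs, and 1802 and 1762 against preadipocytes, also fewer by construction. Higher genes outnumbered lower ones in differentiation at 4932 to 4495, but not with that test, at 2-fold, without dim probe sets (3862 to 4296) or with the covariate (3365 to 3877). With a 4-fold minimum, which takes fewer genes, 523 raised genes (91.3%) fell and 618 lowered genes (87.3%) rose. The covariance was -0.822 without dim probe sets, -0.429 with the mean of all probe sets and -0.587 with the covariate; the cause was not tested. Omitting each array in turn gave 4119 to 4988 higher and 4098 to 4526 lower genes in differentiation, 3137 to 3563 and 2562 to 2824 between the siRNAs, 2819 to 3618 and 2555 to 3103 against preadipocytes, 1290 to 1355 raised genes that fell, 1441 to 1582 lowered genes that rose, and a covariance from -0.569 to -0.535. Replicate numbers did not pair the arrays: same-number deviations correlated at 0.0969, 0.0088 and 0.0359 in differentiation, -0.189, 0.173 and -0.110 between the siRNAs, and -0.0981, -0.0065 and -0.0881 against preadipocytes. A block of replicate number gave 9199, 6314 and 6356 called genes, and shared 9049, 6208 and 6234 of them with the fit without it. Low signal hides changes near the array floor: the filter at 4.89 left 11595 genes. Settings with a pseudocount were not run, as the values were on a log scale.

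Camera with an estimated correlation raised p also where the estimate was below the preset 0.01. For mitochondrial oxidation in differentiation, at an estimate of -0.0233, camera p went from 8.08e-14 to 1.71e-04. For inflammatory genes, at -0.0054, it went from 0.0056 to 0.0222. A lost call therefore does not show that genes of a list moved together. With an estimated correlation, 24 lists were no longer past the threshold at unchanged medians. In differentiation these were insulin signalling (1.10), anti-adipogenic factors (-0.96), receptors and cofactors (0.59), matrix (-1.51), contractile (-2.39), cell cycle (-2.26), brown and beige (0.42) and inflammatory genes (-0.13). Between the siRNAs they were fatty acid synthesis (-0.93), insulin signalling (-0.19), anti-adipogenic factors (0.34), receptors and cofactors (-0.25), matrix (1.25), contractile (1.53), cell cycle (0.47), brown and beige (-0.25) and interferon genes (0.31). Against preadipocytes they were insulin signalling (0.45), adipogenic (0.50) and anti-adipogenic factors (-0.16), matrix (-0.54), contractile (-0.74), cell cycle (-1.56) and brown and beige genes (0.23). For the changes that follow, the cause was not tested. Between the siRNAs, insulin signalling (median -0.19) and interferon genes (0.33) lost their call without dim probe sets, and stress genes gained one after quantile normalisation (0.39). Against preadipocytes, adipogenic factors lost theirs with the mean of all probe sets (0.14), without the 2 arrays of highest Actb difference (0.44) and with the covariate (0.43), and brown and beige genes after quantile normalisation (0.19). Calls gained there were those of receptors and cofactors after quantile normalisation (0.25) and without x and s probe sets (0.30), of inflammatory genes without dim probe sets (-0.50), with the mean of all probe sets (-0.19) and without x and s probe sets (-0.29), and of macrophage genes without x and s probe sets (0.20), without the 2 arrays (0.22) and with the covariate (0.26).

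Omitting 1 array changed 6 list calls. Between the siRNAs, the interferon call (medians from 0.17 to 0.48) ended without control siRNA 2, PPAR gamma siRNA 1 or PPAR gamma siRNA 3, at 0.25, 0.17 and 0.27, and stress genes (0.23 to 0.40) passed without PPAR gamma siRNA 2, at 0.40. Against preadipocytes, receptors and cofactors (0.22 to 0.31) passed without preadipocytes 1 (0.29), preadipocytes 2 (0.28), control siRNA 2 (0.27) or PPAR gamma siRNA 1 (0.22). Inflammatory genes (-0.28 to -0.12) passed without control siRNA 2 (-0.27), stress genes (0.056 to 0.18) without PPAR gamma siRNA 2 (0.17) and macrophage genes (0.11 to 0.22) without PPAR gamma siRNA 3 (0.22). Medians of called lists that moved by over 1.5 times when 1 array was left out were those of inflammatory genes in differentiation without preadipocytes 2 (-0.24), of insulin signalling between the siRNAs without control siRNA 2 or PPAR gamma siRNA 3 (both -0.31), of brown and beige genes there without PPAR gamma siRNA 3 (-0.15), of the interferon list there without PPAR gamma siRNA 1 (0.17) or 2 (0.48), and of anti-adipogenic factors against preadipocytes without PPAR gamma siRNA 1 (-0.24). Over 1200 list values under other settings, 1150 stayed on their side of the threshold, and 11 of those, in lists without a call, changed sign. Over 4471 values of named genes, 80 lost their call, in 21 of 236 gene results, and 29 uncalled values changed sign. The change of Fn1 between PPAR gamma siRNA adipocytes and preadipocytes reversed from 1.27 to -0.050 with the mean of its probe sets, 1 of which was called in the opposite direction.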

Other observations

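Of 1033 genes at least 2-fold higher with PPAR gamma siRNA than control siRNA, 957 had fallen in differentiation, 51 had no differentiation call and 25 had risen. Of 838 genes at least 2-fold lower, 810 had risen, 20 had no call and 8 had fallen. The genes named here were chosen after their values were seen. Without a differentiation call, the melanocyte antigen Mlana was higher with PPAR gamma siRNA by 3.13 ± 0.17, the carnitine synthesis enzyme Bbox1 by 2.81 ± 0.18, the procollagen-processing enhancer Pcolce2 by 2.45 ± 0.25, the matrix gene Ecm2 by 2.42 ± 0.11 and the cytokine Il6 by 1.43 ± 0.18 (n = 3 per group). Igfbp7, an abundant secreted protein, went from 11.43 ± 0.31 to 12.99 ± 0.22 and Apoe from 7.75 ± 0.11 to 9.05 ± 0.06. Lower without a differentiation call were cyclin E2, Ccne2 (-1.95 ± 0.19), and the serine synthesis enzyme Phgdh (-1.86 ± 0.12). Genes that rose in differentiation and further with the siRNA included clusterin, Clu (2.45 ± 0.09), and the cartilage matrix gene Comp (2.36 ± 0.09), and those that fell in both included Wnt5a (-1.78 ± 0.11) and Pla2g7 (-1.26 ± 0.13).

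The tests of shared arrays and of a fixed share of preadipocyte RNA, and the splits of the arrays, were set before their results were seen. The fit with the Actb difference as a covariate was added after the array values had been seen, and the tests on how far lists moved back and on genes that were not lower were chosen only after related results had been seen.

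Knockdown changes opposed differentiation changes across genes. Array noise in the shared control arrays does not account for this alone. The covariance of -0.547 lay below the lowest of 100 simulated values, -0.0093. With separate control arrays, a division chosen after the result was seen, it was at most -0.531. Both rest on the spread between replicates described as technical, so a deviation of a control sample common to the arrays was not tested and stays open. A fixed share of preadipocyte RNA in the PPAR gamma siRNA samples predicted nearly equal falls, from -2.28 to -1.72 at the best share of 79.5%, whereas the falls of the 238 genes raised at least 8-fold ran from -4.01 to 0.11 (5th to 95th percentile), with an SD of observed minus predicted change of 1.25 against a median SE of 0.11. RNA integrity, as read from Actb, left the pattern in place as a covariate: 70.9% of raised genes fell at least 1.5-fold with it and 72.2% without. A hypothesis is that PPAR gamma depletion may bring a partial return towards the preadipocyte state; effects of the siRNA on other transcripts stay open and were not tested, which arrays with another siRNA against Pparg, or with Pparg restored, would decide.

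Lists differed in how far they moved back, with cell cycle genes at 24.2%. The 22 members of the cell cycle list moved back -26.3 percentage points relative to the 50 genes nearest in size of the differentiation change and signal level. This lay outside -14.6 to 15.7 for random lists of that size. Random lists hold unrelated genes, whereas the cell cycle list had an estimated correlation of 0.55 between its genes. The range is therefore likely too narrow, and it cannot exclude size and signal level as explanations. For fatty acid and triglyceride synthesis the value was -17.4 over 19 members, inside -18.9 to 16.5, so these explanations cannot be told apart from a difference of the list itself with so few genes. Preadipocyte RNA at the share that fits the raised genes predicted a median rise of 2.04 in cell cycle genes, and the rise was 0.52, with a median difference of -1.38 (SD 0.54) and 22 of 22 members below the prediction. Matrix genes (1.67 against a predicted 3.30, median difference -1.23) and contractile genes (1.70 against 2.59, -0.56) also rose less than predicted, so the shortfall is not particular to cell cycle genes, and no biological explanation for the difference between lists was tested.

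Of 238 genes raised at least 8-fold in differentiation, 24 were not lower with PPAR gamma siRNA, and 8 of them rose, including the corticotropin receptor Mc2r (0.95 ± 0.09), Phkg1 (0.88 ± 0.15) and Apoc1 (0.41 ± 0.10), all 3 named after their values were seen. Signal saturation does not account for these genes, as their median control level was 8.76, with the highest at 12.34, and genes that fell had a median of 10.25. A probe set that fails to follow its gene was checked for 10 of these genes. Of their 19 other probe sets that were called higher in differentiation, 2 (10.5%) were called lower with PPAR gamma siRNA. These probe sets have lower means than the one used, and one without a call may still have fallen, so the explanation is not excluded. For the other 14 genes, which have no such probe set, it was not testable and stays open. The cholesterol exporters Abca1 (0.22 ± 0.15) and Abcg1 (-0.28 ± 0.17), also named after their values were seen, were among the genes without a call. No biological explanation was tested.

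For each comparison of 3 arrays with 3, the 10 splits of the arrays into equal groups are too few for a share under 0.05. Every other split also mixes the groups compared, so their differences count as spread in it. Few calls in those splits were therefore fixed in advance, and they lend no weight to the counts. In differentiation the real split called 9427 genes and the highest other split 0, with 1 of 10 splits calling as many. The corresponding numbers were 6534 and 0 between the siRNAs, and 6632 and 0 for PPAR gamma siRNA adipocytes against preadipocytes, again with 1 of 10 splits each.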
